A study of Mus musculus with 2 samples.

How the data were processed

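Total RNA from whole midbrain of newborn mice (postnatal day 0) was sequenced in 2 libraries, which the labels describe as biological replicates from independent isolates. The labels give the strain as B6NTac;B6NCrl/Lap, pooled males and females, a pool of 15 animals for replicate 1 and a pool of unstated size for replicate 2. Per the labels, the libraries were stranded, made from RNA over 200 nucleotides after removal of ribosomal RNA, and read as pairs of 101 bases. Per the labels, both libraries received spike-in RNAs, synthetic molecules of known sequence, from the same reference set. The 24 spike-ins with a summed count of at least 1000 had an SD of 0.24 in their log2 ratios between the libraries, and all 50 with a summed count of at least 20 an SD of 1.52. Because no step selected for poly(A) tails, RNA without a tail, such as histone mRNA and structured RNA, was measured too.

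Per the notes deposited with each sample, the authors quantified genes and transcripts on assembly mm10 with GENCODE release M4, from alignments to the transcriptome. The aligner, the quantification program and their versions are not given in the sources used here. The deposited estimated counts (expected counts) need not be whole, because a read that fits several genes is divided among them. The deposited TPM values, the transcript abundance scale used throughout, divide each count by an effective length and sum to the same total in each library over all rows, spike-ins included. The authors also deposited FPKM values per gene and transcript, which were used here only as an alternative. The percent of each gene carried by each transcript was taken as deposited, and the lower and upper credibility bounds of TPM in the same tables were used only to describe uncertain genes. The effective length was shorter than the gene length by a median of 280.2 bases in replicate 1 and 280.3 in replicate 2, over genes with an effective length above 1 kilobase. For RNAs near that length a few counts give a high TPM, or a TPM of 0 where no effective length was left.

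Each gene table held 69691 lines. Of these, 43346 carried Ensembl gene identifiers, 96 were spike-ins, 1 was the phiX174 phage genome used as a sequencing control, and 26248 were numbered without a gene name and at 0 in both libraries. Symbols, classes and coordinates came from GENCODE release M21 on the same assembly (GRCm38), which matched 42462 gene identifiers. The 884 identifiers that did not match held 0.129% of the counts in replicate 1 and 0.119% in replicate 2. Of 103639 Ensembl transcripts, 101510 matched. Gene classes were small structured RNA, mitochondrial rRNA and mRNA, replication-dependent histones in the histone clusters, hemoglobins, long noncoding RNA, pseudogenes and other protein-coding genes.

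Depth was 46685706 counts in replicate 1 and 72779229 in replicate 2, of which 46119063 and 72011300 fell on genes. A gene at 0 could hold up to 3 counts by sampling alone, or 0.0651 CPM (counts divided by the library total and rescaled) in replicate 1 and 0.0417 in replicate 2. Floors here cover counting error only, since reads without molecular identifiers are not independent molecules. The binomial and bootstrap intervals given below take genes or spike-ins as units, and do not cover variation between isolates. A chi-square test over 18554 genes with a summed count of at least 10 showed that the libraries were not 1 library deposited 2 times (chi-square 954101 on 18553 degrees of freedom, or 51.4 per degree of freedom).

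The labels define 1 group, so no groups were compared. Before the data were examined, 41 gene lists, 20 gene pairs, 20 genes for transcript use, the tests of the main comparisons and a rule for the genes to be named were fixed. The tests on the spike-ins and some of those in the closing part were chosen after the data were seen. The rule named up to 6 members per list with the highest mean TPM, members below 1 TPM in both libraries where absence was described, both genes of each pair, the 15 highest genes outside and the 5 highest within the mitochondrial, histone and structured classes, and the leading transcript of each transcript-use gene. Of genes that differed between the libraries with a mean TPM of at least 1, it named the 10 with the largest log2 ratio in each direction. Some genes that the rule names are not reported here. Other genes named in the text, such as the mitochondrial copies, family leaders and epidermal genes, were chosen after their values were seen.

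Levels are the mean and SD of TPM over the 2 libraries. A gene counted as detected at a TPM of at least 1 in both. Pairs were compared within a library as the log2 ratio of TPM + 0.1, and called where the ratio was at least 2-fold the same way in both libraries. Pearson and Spearman coefficients were computed across genes on log2(TPM + 1). The biological coefficient of variation came from edgeR 4.0.16 with trimmed-mean (TMM) scaling on estimated counts rounded to whole numbers, over 16391 genes that passed its expression filter.

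Genes were compared between the libraries with a two-sided exact conditional binomial test of rounded counts at TMM-scaled library sizes, with Benjamini-Hochberg adjustment over 17574 genes with a summed count of at least 20. A gene was called at an adjusted p below 0.05 and a log2 ratio of at least 1 in size, computed with 0.5 added to each count. This test compares the 2 libraries and covers counting error only. Of the lists, 34 had at least 4 members at 1 TPM or more in either library. Their median log2 ratio, on TMM-scaled TPM + 1, was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and described as outside where it lay beyond the central 99%. The log2(TPM + 1) scale understates the change of low genes. For noise, added after the data were seen, members of a list called with the spike-in excess of their count range were counted against the share of such calls among genes of like summed count, in 10 bins, with an exact p multiplied by the number of lists and directions.

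The exact test was tested on simulated libraries with the real gene means and depths. In these, 200 genes with an expected summed count of at least 200 differed, so recovery at lower counts was not tested. With independent reads over 17579 genes the exact test called 100.0% of genes changed 2.5-fold and 100.0% of those changed 4-fold, and 1 unchanged gene. With reads clumped to the degree seen in the spike-ins it called 1796 unchanged genes of 17364. The spike-in excess was the mean chi-square per degree of freedom of the spike-ins at summed counts of 20 to 1000, 13.6. Dividing counts by it lowered the false calls to 1 unchanged gene, with 74.0% of the 2.5-fold and 94.0% of the 4-fold genes called. Reads of all genes had been clumped by that same factor, so the low number of false calls was set by the design. With a spread of 20% between the libraries the exact test called 507 unchanged genes of 17539, and 177 with the spike-in excess. The excess was larger at higher counts, so a further alternative divided counts by the excess of the spike-ins in the gene's own range: up to 1000 counts, 1000 to 10000 (46.8) and above (58.1). The coefficient of variation came out at 21.9% where 20% was set, over 17127 genes, and at 9.6% over 17253 genes and 21.0% over 16661 genes with no spread set beyond the changed genes, for independent and clumped reads. In simulated lists of 10 members, 0 of 200 unchanged lists and 200 of 200 lists shifted by 1 lay outside. There the noise was independent between genes and alike at all expression levels. The lists found outside in the data had fewer members or smaller shifts, so this simulation does not test them.

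Alternatives fixed beforehand were other TPM minimums, FPKM, other pseudocounts and count filters, DESeq2 1.42.0 size factors, no scaling, TPM rescaled to protein-coding genes, protein-coding transcripts only, counts per kilobase, and each library alone. Alternatives added after the data were seen were protein-coding genes only, genes of at least 500 bases, scaling to the spike-ins, counts divided by the spike-in excess or by that of their count range, and detection on rescaled TPM. Near-identical nuclear copies of mitochondrial genes were found with blastn 2.17.0 (identity of at least 97% over at least 150 bases) among M21 pseudogene transcripts; they were first weighed as a pattern for the closing part and then given as values only, and the epidermal genes were taken up in their place after the calls were seen. Python 3.11.15, scipy 1.17.1 and R 4.3.3 were used. The deposited notes were read for the build and annotation only, and alignments and signal tracks were not analysed here.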

Results

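The data describe the RNA content of the whole mouse midbrain on the day of birth, measured by total RNA sequencing in 1 group of 2 libraries made from independent tissue isolates of pooled animals. Replicate 1 held 46685706 counts and replicate 2 held 72779229. With 1 group, the questions the design allows are which genes and cell types the tissue expressed, at what levels, and how closely the isolates matched. Values below are TPM, given as mean ± SD (n = 2), unless another unit is named. They were not scaled between the libraries, and TPM ran lower in replicate 2, by a median log2 ratio of -0.23 over all genes. A small SD therefore need not mean that a gene matched between the isolates. Lhx2, with an SD of 0.00707, had a log2 ratio of 0.20 on scaled counts.

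By TPM, most of the transcript molecules estimated in the midbrain were short structured RNAs, while most counts came from protein-coding genes. Rn7sk, the RNA of the 7SK complex that restrains transcription elongation, reached 400900 ± 1294 TPM (chromosome 9, 78175303 to 78175633, mm10). Rn7s1 and Rn7s2, copies of the signal recognition particle RNA, each reached 124200 ± 12230, and Rpph1, the RNA of ribonuclease P, 40740 ± 7815. These RNAs are 300 to 331 bases long, near the 280 bases by which effective lengths fell short of gene lengths. Their TPM, and the share of their class, therefore rest on short effective lengths and are uncertain as numbers of molecules. The mitochondrial large ribosomal RNA mt-Rnr2 stood at 49510 ± 3836 TPM and took 11.2% of the counts in replicate 1 and 11.9% in replicate 2.

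Small structured RNA as a class took 70.9% ± 2.31 of TPM and 5.27% ± 0.738 of counts. Other protein-coding genes took 19% ± 2.11 of TPM and 76.5% ± 1.28 of counts, so the choice of unit decides which class leads. Mitochondrial rRNA took 5.96% ± 0.496 of TPM and 12.7% ± 0.512 of counts. Histone genes of the replication-dependent clusters, whose mRNA lacks a poly(A) tail, took 0.591% ± 0.0755 of TPM, and 57 of 67 were detected. Long noncoding RNA took 0.558% ± 0.0950 and hemoglobins 0.0656% ± 0.00960 of TPM. Because the structured RNAs fill the TPM scale, a TPM here corresponds on average to 5.11 TPM on a scale of protein-coding genes alone (4.74 in replicate 1 and 5.48 in replicate 2). The reads of Rn7s1 and Rn7s2 were divided evenly between near-identical copies, with 224784 counts each in replicate 1, so the values of the separate copies are uncertain.

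**Figure D1:**
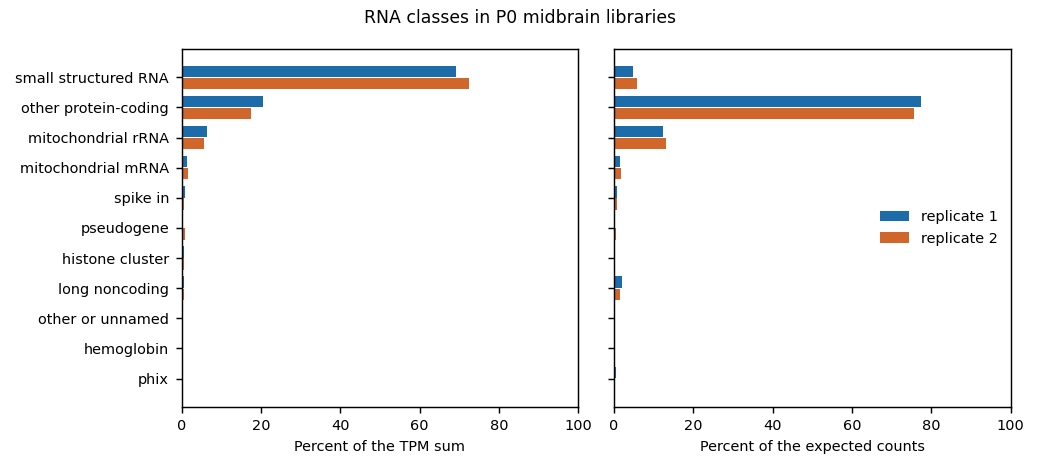
Share of each RNA class in the TPM sum (left, percent) and in the expected counts (right, percent), with 1 bar per library. Small structured RNA leads in TPM at 70.9% and other protein-coding genes lead in counts at 76.5%.

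In all, 12011 of 43346 genes were detected, among them 11479 other protein-coding genes, 213 long noncoding genes and 154 pseudogenes. Tuba1a, the main alpha-tubulin of young neurons, led the other protein-coding genes at 4377 ± 90.7 (ENSMUSG00000072235.5, chromosome 15, 98949837 to 98953703). Of further tubulins, Tubb2a stood at 1232 ± 28.3, Tubb2b at 1156 ± 106, Tubb3 at 771 ± 63.0 and Tubb5 at 689 ± 88.5. Nnat, an imprinted gene of the developing brain, stood at 1629 ± 255, the elongation factor Eef1a1 at 1317 ± 260, Actb at 1031 ± 111, the ATP synthase subunit Atp5b at 987 ± 191, the ribosomal protein Rps26 at 761 ± 96.7 and the chaperone Hspa8 at 752 ± 3.37. The annotated lincRNA Gm26917 (chromosome 17, 39843013 to 39846341) stood at 1509 ± 108. It held 334807 counts in replicate 1 and 515243 in replicate 2, which are part of the long noncoding class above. Whether these reads come from a lincRNA was not tested.

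The remaining genes among the 15 highest were pseudogenes on chromosome 1 that copy mitochondrial genes. Gm10925, at 1292 ± 282, copies mt-Atp6; Gm28661, at 993 ± 681, copies mt-Co2; and Gm28437, at 954 ± 920, copies mt-Co3, each identical to its mitochondrial counterpart over its aligned length. Gm28661 held 15720 counts in replicate 1 and 83807 in replicate 2 while mt-Co2 held 29266 and 22223, and Gm28437 held 11718 and 114495 counts while mt-Co3 held 109934 and 114214. The summed counts of mt-Co2 and its copy differed between the libraries by a log2 ratio of 0.63 (replicate 2 over 1), and those of mt-Co3 and its copy by 0.30. The 6 mitochondrial protein genes without such a copy had a median of 0.43 (range 0.11 to 1.37). The level of each member of these pairs is therefore uncertain. mt-Atp8, shorter than most fragments, was listed at 0 TPM in replicate 1 on 222 counts and at 4774 TPM in replicate 2 on 878 counts, so its TPM cannot be used.

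The midbrain identity of the tissue was measured with transcription factor genes of the midbrain and of its neighbours. Of 22 midbrain patterning genes, 17 were detected, led by Meis2 at 26.4 ± 0.820, Otx2, which specifies forebrain and midbrain, at 17.1 ± 1.72, Tcf7l2 at 15.2 ± 4.19, Tal1 at 13.8 ± 2.65, Pax5 at 11.3 ± 2.41 and En2 at 11.0 ± 0.580. Foxa1, Nkx6-1, Tal2 and Helt lay below 1 in both libraries. Of 16 forebrain genes 5 were detected: Lhx2 at 16.5 ± 0.00707, Bcl11b at 11.1 ± 0.962, Six3 at 2.37 ± 0.0354, Neurod6 at 1.54 ± 0.417 and Emx2 at 1.26 ± 0.0636, while Dlx1 stood at 1.20 ± 0.969. Another 10 lay below 1 in both libraries.

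Most hindbrain and spinal cord genes were low. Of 14, 10 lay below 1 in both libraries. Hoxd3 was at 0 counts in replicate 1 and 174 in replicate 2, Hoxa5 at 2 and 432, Hoxb3 at 46 and 419, Hoxa2 at 39 and 117, and Hoxb8 at 0 and 51; Hoxa2 passed no 2-fold call, and Hoxb8 lost its call with the spike-in excess given below. Of 9 cerebellar genes 4 were detected, Zic1 at 23.2 ± 5.12, Zic4 at 12.6 ± 1.26, Car8 at 4.36 ± 2.03 and Pcp2 at 4.15 ± 2.73; Neurod1 stood at 1.90 ± 1.62 and Skor2 at 0.820 ± 0.707.

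Genes of several transmitter types were present. All 4 GABA genes were detected, among them the synthetic enzymes Gad1 at 33.4 ± 7.38 and Gad2 at 12.8 ± 5.30, and the vesicular transporter Slc32a1 at 11.6 ± 0.120. Among the vesicular glutamate transporters, Slc17a6 stood at 35.7 ± 6.56, Slc17a8 at 0.575 ± 0.318 and Slc17a7 at 0.435 ± 0.0354. Of 10 dopaminergic genes 9 were detected, among them the decarboxylase Ddc at 6.24 ± 1.73, Aldh1a1 at 5.40 ± 2.07, the rate-limiting enzyme Th at 5.03 ± 0.0849, the dopamine transporter Slc6a3 at 4.92 ± 0.580, Slc18a2 at 4.20 ± 0.354 and Ret at 3.59 ± 0.233; Pitx3 stood at 0.485 ± 0.120.

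The serotonin transporter Slc6a4 stood at 6.37 ± 1.86, Tph2, which makes serotonin in the brain, at 2.60 ± 1.34, and Htr1a at 1.98 ± 0.262, with Fev at 0.720 ± 0.141. Of the 3 noradrenergic genes none was detected in both libraries: Dbh stood at 1.57 ± 0.976, Slc6a2 at 1.06 ± 0.467, and Hand2 at 0 counts. Among 7 cholinergic and oculomotor genes 3 were detected, Prph at 2.06 ± 0.0212, Isl1 at 1.86 ± 0.573 and Slc5a7 at 1.05 ± 0.0707, while Slc18a3 stood at 1.12 ± 0.361 and Chat at 0.125 ± 0.0495. Glycine receptor genes were led by Glra2 at 18.3 ± 1.82, Glrb at 17.8 ± 0.304 and Glra3 at 2.92 ± 0.262, above Slc6a5 at 0.915 ± 0.601 and Glra1 at 0.615 ± 0.290. Of 15 neuropeptide genes 9 were detected, with Sst at 113 ± 3.83, Cck at 23.8 ± 9.77, Npy at 22.0 ± 2.94, Tac1 at 16.7 ± 2.89, Penk at 7.68 ± 0.552 and Adcyap1 at 4.61 ± 1.15.

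Genes of young neurons stood higher than those of mature neurons. All 14 immature neuron genes reached 10 TPM in both libraries, with a median of 174 ± 35.7; after Nnat, Tubb2b and Tubb3 came Marcksl1 at 308 ± 24.9, Stmn1 at 288 ± 78.4 and Dpysl3 at 258 ± 44.3. All 11 mature neuron genes were detected, with a median of 15.0 ± 2.86, led by Map2 at 288 ± 46.8, the vesicle protein Syp at 91.1 ± 1.09, the neurofilament Nefl at 81.4 ± 3.83, Snap25 at 45.5 ± 1.39, Syt1 at 23.3 ± 4.20 and Thy1 at 13.6 ± 4.91. Of 15 ionotropic glutamate receptor genes 14 were detected, led by Gria2 at 41.3 ± 7.79, Grik5 at 29.1 ± 5.09, Grin3a at 26.7 ± 3.90, Grin1 at 26.2 ± 0.856, Grik2 at 25.6 ± 2.20 and Gria4 at 24.8 ± 4.94; Grin2c stood at 0.680 ± 0.0849. All 11 GABA-A receptor genes were detected, among them Gabrb2 at 25.1 ± 5.77, Gabra5 at 15.4 ± 0.842, Gabra3 at 12.5 ± 5.97 and Gabra2 at 8.86 ± 0.990.

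Genes that steer growing axons were nearly all expressed. All 16 Eph receptor and ephrin genes were detected, led by Ephb2 at 34.4 ± 3.73, Efnb3 at 29.8 ± 4.62, Ephb1 at 18.2 ± 3.73, Efna3 at 16.2 ± 0.919, Epha4 at 13.4 ± 1.73 and Epha5 at 11.5 ± 2.91. Of 20 other guidance genes 19 were detected, led by Plxna1 at 44.4 ± 3.52, Robo2 at 32.6 ± 9.36, Sema3f at 23.4 ± 3.17, Robo1 at 16.8 ± 3.80, Slit1 at 14.5 ± 1.28 and Ntn1 at 13.5 ± 1.80; Robo3, a receptor of axons that cross the midline, stood at 0.535 ± 0.0212.

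Progenitor and glial genes were detected beside the neuronal ones. All 11 progenitor genes were detected, led by Fabp7 at 175 ± 61.2, Vim at 97 ± 6.59, the glutamate transporter Slc1a3, also on the astrocyte list, at 35.5 ± 0.269, Hes5 at 22.4 ± 2.98, Sox2 at 14.2 ± 1.19 and Notch1 at 11.2 ± 1.12. Of 13 proliferation genes 9 were detected, with Pcna at 22.7 ± 1.41, Cdk1 at 5.45 ± 2.11, Top2a at 3.42 ± 0.636, Ccnb1 at 3.42 ± 1.01, Ccna2 at 3.18 ± 0.608 and Mcm5 at 2.74 ± 0.0636. All 12 astrocyte genes were detected, with Glul at 63.7 ± 4.38, Aldoc at 61.2 ± 6.68, Aldh1l1 at 23.0 ± 0.757, Slc1a2 at 19.7 ± 1.44 and Agt at 17.6 ± 2.08. Of 8 genes of oligodendrocyte precursors 7 were detected, among them Ptprz1 at 39.9 ± 6.65, Olig1 at 34.3 ± 2.37, Pdgfra at 10.2 ± 0.636, Olig2 at 9.55 ± 2.28, Cspg4 at 5.52 ± 0.134 and Gpr17 at 5.40 ± 1.49.

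Myelin genes were lower than those of the precursors. Of 12, 6 were detected, among them Cnp at 12.1 ± 0.672, Cldn11 at 10.6 ± 3.19, Mbp at 9.34 ± 3.68, Mag at 1.94 ± 1.12 and Ugt8a at 1.14 ± 0.0212. Aspa, Myrf, Mobp, Ermn, Mog and Opalin lay below 1 in both libraries, and Opalin had no counts in either. Of 12 microglial genes 11 were detected, among them C1qc at 14.0 ± 0.891, C1qb at 13.1 ± 2.97, C1qa at 9.65 ± 0.997, Csf1r at 5.53 ± 1.02 and Tyrobp at 3.45 ± 0.311.

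Vessel and membrane cells were also represented. All 9 endothelial genes were detected, with Cldn5 at 32.1 ± 9.19, Mfsd2a at 10.3 ± 0.347, Esam at 6.87 ± 2.12, Kdr at 4.32 ± 1.24, Cdh5 at 4.05 ± 0.891 and Pecam1 at 3.55 ± 0.460. Of 8 mural genes 5 were detected in both libraries, led by Vtn at 23.3 ± 1.78, Rgs5 at 10.5 ± 2.40 and Pdgfrb at 4.36 ± 0.651, then Kcnj8 at 1.96 ± 0.644 and Abcc9 at 1.92 ± 0.347; Acta2 stood at 2.48 in replicate 1 and 0.790 in replicate 2, and was called higher in replicate 1 (log2 ratio -1.37), though not with the spike-in excess given below. All 10 meningeal fibroblast genes were detected, led by Ptgds at 485 ± 135, the growth factor Igf2 at 74.1 ± 6.5, the collagens Col3a1 at 25.0 ± 3.34 and Col1a2 at 22.7 ± 7.36, Slc6a13 at 11.1 ± 0.297 and Dcn at 10.4 in replicate 1 and 9.62 in replicate 2. Among 8 choroid plexus genes, Ttr stood at 14.4 in replicate 1 and 163 in replicate 2, Folr1 at 1.62 ± 0.806, Sostdc1 at 1.48 ± 0.651, Aqp1 at 1.44 ± 1.39, Clic6 at 0.540 ± 0.127 and Kl at 0.445 ± 0.0212. Among 7 ependymal genes 2 were detected, Foxj1 at 6.01 ± 1.24 and Tmem212 at 1.85 ± 0.127; Dynlrb2 stood at 1.44 ± 1.95, Pifo at 0.790 ± 0.467, Rsph1 at 0.610 ± 0.113 and Ccdc153 at 0.340 ± 0.184.

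Adult hemoglobin genes were high, while muscle, cartilage, bone and pituitary genes were low or absent. The hemoglobin genes were Hba-a2 at 332 ± 67.6, Hba-a1 at 145 ± 35.8, Hbb-bs at 140 ± 16.3 and Hbb-bt at 36.8 ± 8.61, with Alas2 at 2.97 ± 1.75 and Slc4a1 at 0.135 ± 0.0919, while the embryonic Hbb-bh1 had no counts in either library. Of 9 skeletal muscle genes 1 was detected, Acta1 at 3.38 ± 1.12, above Ckm at 0.620 ± 0.834, Myh8 at 0.390 ± 0.240, Tnnt3 at 0.270, Actc1 at 0.240 ± 0.339 and Mylpf at 0.235 ± 0.0636. Of 7 cartilage and bone genes 1 was detected, Col2a1 at 3.09 ± 0.248, above Acan and Col9a1, both at 0.385, and Matn1, Bglap and Comp under 0.1. No pituitary gene of 8 was detected: Pomc stood at 0.435 ± 0.0636, Gh at 0.120 ± 0.170 and Lhb at 0.105 ± 0.148, and Prl, Tshb and Cga had no counts. Xist, expressed from the inactive X chromosome of females, stood at 19.4 in replicate 1 and 6.76 in replicate 2, and its antisense Tsix at 0.0200 ± 0.0141. All 4 Y-linked genes were detected, Eif2s3y at 8.14 ± 2.88, Ddx3y at 4.14 ± 0.339, Uty at 3.73 ± 0.658 and Kdm5d at 2.88 ± 0.0141; the labels name pooled males and females.

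Immediate early genes were low, while several heat shock and hypoxia genes stood much higher. Of 9 immediate early genes 4 were detected, Dusp1 at 8.78 ± 0.262, Junb at 2.62 ± 0.354, Fos at 2.38 ± 0.446 and Nr4a1 at 1.39 ± 0.00707, with Arc at 1.07 ± 0.347 and Egr1 at 0.830 ± 0.113. All 6 heat shock genes were detected; after Hspa8 came Hsp90aa1 at 126 ± 31.0, Dnajb1 at 11.2 ± 1.48, Hspa1a at 6.92 ± 0.735, Hsph1 at 6.26 ± 2.09 and Hspa1b at 3.46 ± 0.163. Of 10 hypoxia genes 7 were detected, led by Ldha at 67.9 ± 6.84, Bnip3 at 45.3 ± 4.33, Pgk1 at 43.9 ± 12.7, Slc2a1 at 23.5 ± 0.976, Vegfa at 17.3 ± 2.54 and Pdk1 at 10.9 ± 1.94.

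Imprinted and long noncoding genes reached high levels. Of 19 imprinted genes 17 were detected; after Nnat came the noncoding Rian at 665 ± 124 and Meg3 at 275 ± 86.8, then Ndn at 239 ± 19.8, Mest at 152 ± 13.7 and Snrpn at 110 ± 14.3. Of 10 long noncoding genes measured 9 were detected, with Malat1 at 398 ± 113, Miat at 46.6 ± 22.3, Snhg11 at 43.7 ± 17.8 and Gas5 at 43.2 ± 6.09 beside Rian and Meg3; Snhg1, Rmst and Peg13 did not match a symbol and were not analysed here. Of 12 mouse homologs of Parkinson disease genes 11 were detected, among them Uchl1 at 382 ± 63.5, Atp13a2 at 78.8 ± 2.91, Pink1 at 51.1 ± 4.51, Dnajc6 at 42.8 ± 2.14 and Park7 at 34.3 ± 1.80; Lrrk2 stood at 0.695 ± 0.0919. Over all 41 lists, 27 had a median of at least 1 TPM in both libraries.

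**Figure D2:**
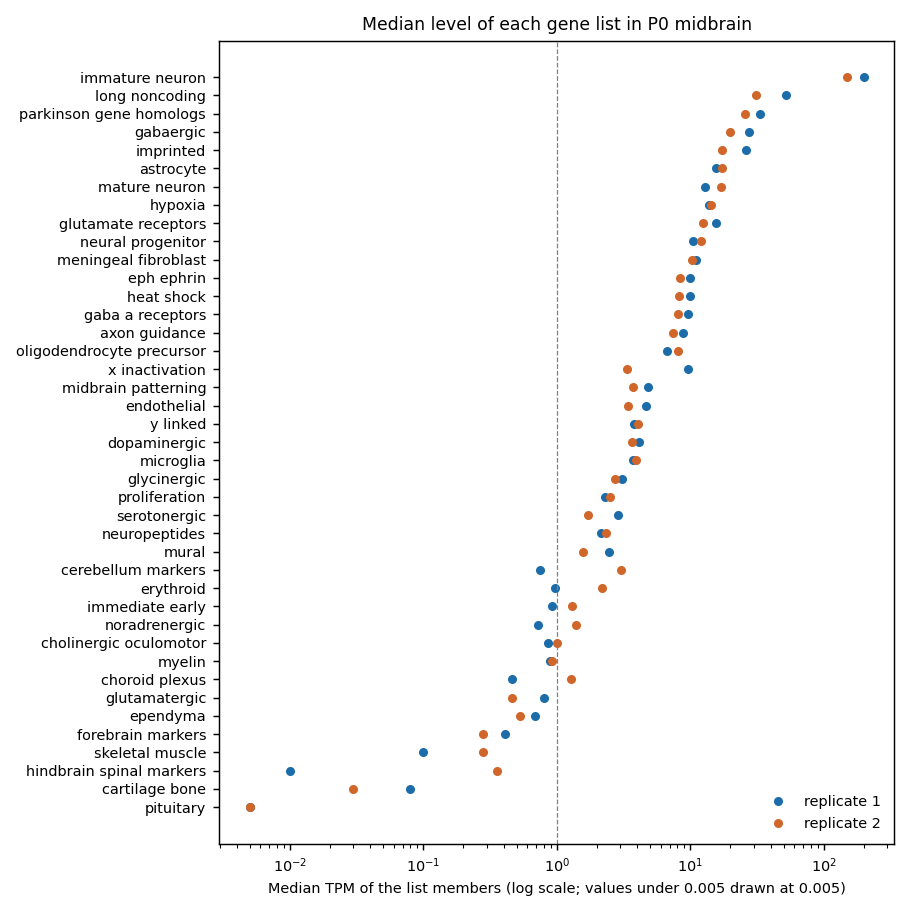
Median TPM of the members of each of the 41 gene lists (log scale), with 1 point per library and a dashed line at 1 TPM. Immature neuron genes lie highest, with a mean of the library medians of 174, and pituitary genes lowest, at 0.

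Pairs of related genes were compared within each library, where no scaling between libraries is needed. Of 20 pairs, 16 differed by at least 2-fold the same way in both libraries. Slc17a6 exceeded Slc17a7 by a log2 ratio of 6.05 ± 0.36 (4.66 with a pseudocount of 1) and Slc32a1 by 1.60 ± 0.28. The neonatal NMDA receptor subunit Grin2b exceeded the later Grin2a by 2.62 ± 0.07, and the sodium channel Scn3a exceeded Scn8a by 2.41 ± 0.18. The chloride exporter Slc12a5 stood at 86.7 ± 1.98 against 4.95 ± 1.67 for the importer Slc12a2, a log2 ratio of -4.14 ± 0.52 for Slc12a2 over Slc12a5. On protein-coding transcripts alone that ratio was -3.15. Dcx, of migrating neurons, exceeded Rbfox3, of mature neurons, by 2.57 ± 0.79, and Gad1 exceeded Gad2 by 1.42 ± 0.29.

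Slc1a3 exceeded Gfap by 2.73 ± 0.46, the methyltransferase Dnmt3a exceeded Dnmt3b by 4.19 ± 0.37, Ndn exceeded H19 by 2.20 ± 0.19 and Igf2 exceeded its receptor Igf2r by 3.29 ± 0.36. Dnmt3a over Dnmt3b was 3.36 with a pseudocount of 1 and 5.0 on protein-coding transcripts alone. En2 exceeded Hoxb3 by 3.90 ± 1.71, where Hoxb3 had 46 counts in replicate 1. Pdgfra and Hbb-bs were also called against Mog (0 and 2 counts) and Hbb-bh1 (0 counts in both), for which no fold is given. Gria2 exceeded Gria1 by 1.46 ± 0.16, but by 0.24 on protein-coding transcripts alone, which ended the call. The 4 pairs without a call included Th over Tph2 at 1.02 ± 0.73, Slc6a3 over Slc6a4 at -0.34 ± 0.25 and the splicing factors Ptbp2 over Ptbp1 at 0.47 ± 0.20; the last rose to 1.24 on protein-coding transcripts alone. The smallest two-sided p that an exact sign-flip permutation over 2 libraries can give is 0.5, so no p is given.

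**Figure D3:**
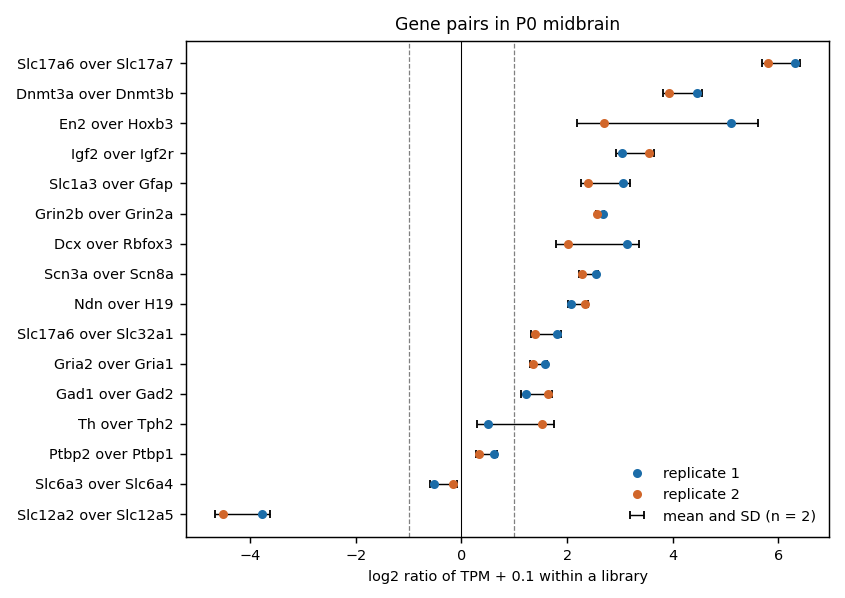
Log2 ratio of TPM + 0.1 within a library for 16 gene pairs, with 1 point per library and bars for the mean and SD (n = 2); dashed lines mark 2-fold, and the pairs with Mog and Hbb-bh1 are among those left out. Slc17a6 over Slc17a7 lies highest at 6.05 and Slc12a2 over Slc12a5 lowest at -4.14.

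Transcript use followed 1 leading transcript for many neuronal genes. Over 5169 genes with at least 5 TPM and several expressed transcripts, the leading transcript was the same in both libraries for 86.0% (exact 95% binomial interval 85.0 to 86.9). That interval takes genes as independent and does not cover variation between isolates. The leading transcript carried a median of 67.5% ± 0.19 of the gene. Of 20 genes fixed for this comparison, 17 had the same leading transcript in both libraries. Mapt, the tau gene, used Mapt-204 for 97.9% ± 0.354, Snap25 used Snap25-201 for 91.4% ± 0.403, Bin1 used Bin1-201 for 90.2% ± 1.41, and Dlg4 used Dlg4-201 for 82.7% ± 0.120. Rtn4-205 carried 74.4% ± 1.74 of Rtn4, Ntrk2-201 67.3% ± 6.10 of Ntrk2, Dclk1-201 64.1% ± 0.290, Clta-204 63.4% ± 2.30, Nfasc-202 61.2% ± 4.26 and Cltb-201 60.6% ± 1.19. Ptprz1-201 was the transcript listed with a value for Ptprz1. Camk2b-209 carried 43.9% ± 4.38, Nrxn3-205 41.6% ± 7.21, Gria2-201 26.8% ± 4.53 and Ank3-244 22.2% ± 1.90 of their genes, while Mbp-205 carried 65.2% in replicate 1 and 33.3% in replicate 2. The leading transcripts of Ank2 and Map2 were among those that differed between the libraries. Transcript shares rest on reads divided among overlapping models and are estimates.

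Between the 2 libraries, gene levels followed each other closely, and a limited set of genes stood apart. Across 13051 genes at 1 TPM or more in either library, Pearson r was 0.953 and Spearman rho 0.957, and across 12175 protein-coding genes 0.971 and 0.968; genes are not independent replicates. The biological coefficient of variation as estimated between the libraries was 22.6% (17% as the median of the trend), and 19.8% for protein-coding genes. Simulated libraries with clumped reads and no spread of unchanged genes gave 21% (15% for the trend), so the value need not come from the isolates. Of 17574 genes tested, 2275 differed at least 2-fold past counting error, 999 higher in replicate 1 and 1276 higher in replicate 2. The spike-ins, synthetic RNAs from the same reference set in both libraries, varied beyond counting error. At summed counts of 20 to 1000 their mean chi-square per degree of freedom, a ratio of variances, was 13.6. With counts divided by that excess, 30 and 90 genes were called. In simulated libraries with a spread of 20%, that test still called 177 unchanged genes. The excess of the spike-ins was 46.8 at 1000 to 10000 counts and 58.1 above, against 33.0 and 126 for protein-coding genes. Yet the SD of log2 ratios fell over these ranges, from 2.12 to 0.31 and 0.13 for spike-ins. For protein-coding genes it fell from 1.56 to 0.31 and 0.22. With the excess of each gene's count range, 11 and 33 genes were called. Genes of up to 1000 counts keep the same factor there, and lost calls only through the adjustment over all genes.

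Genes of hindbrain, cerebellum, choroid plexus and red blood cells were higher in replicate 2. In the exact binomial test, Ttr, the choroid plexus carrier of thyroid hormone, had 1039 and 21655 counts (log2 ratio 3.77), Aqp1 83 and 806 (2.66), Neurod1 141 and 1056 (2.29), Skor2 70 and 534 (2.32), Car8 799 and 2936 (1.27) and Hoxb3 46 and 419 (2.57); these were called also with the spike-in excess, but Neurod1 and Car8 not with that of their count range. Hoxd3 (ENSMUSG00000079277.5, chromosome 2, 74711927 to 74748442) likewise kept its call only with the excess of 13.6. Ppp1r17, also on the cerebellar list, was called higher in replicate 1 (20 and 2 counts, log2 ratio -3.64), though not with the spike-in excess. Dbh had 154 and 729 counts, a call kept in both forms, and Slc6a2 326 and 1145, lost with the excess of its count range. Of 8 skeletal muscle genes tested, 5 were called higher in replicate 2, among them Ckm (3 and 195 counts), and 2 with the excess of 13.6, neither with that of its count range. Among the 34 lists compared, the median log2 ratio was 1.43 for the 4 of 14 hindbrain and spinal genes at 1 TPM in either library, above the central 99% of random lists (-0.86 to 0.86), 1.09 for choroid plexus genes (-0.46 to 0.60), 0.97 for cerebellar genes (-0.40 to 0.44), 0.74 for erythroid genes (-0.31 to 0.52) and 0.32 for astrocyte genes (-0.21 to 0.26). Over all members with counts the median was lower, 0.39 for hindbrain and spinal genes (-0.24 to 0.24), 0.65 for choroid plexus genes (-0.35 to 0.39) and 0.70 for cerebellar genes (-0.27 to 0.30). For erythroid genes it was 0.46 (-0.23 to 0.30). Of 7 erythroid genes tested, 3 were called higher in replicate 2, and 0 with the spike-in excess. The long noncoding list, with Malat1, Meg3 and Miat, was higher in replicate 1 at -0.31 (-0.27 to 0.36). The other 28 lists lay inside their ranges, with midbrain patterning at 0.08, dopaminergic genes at 0.08 and forebrain genes at 0.13. If genes varied independently, 0.34 of 34 lists would lie outside by chance. Members of a list can vary together and some lists share members, so that number does not exclude chance. The remaining 7 lists, noradrenergic and muscle genes among them, had too few members at 1 TPM.

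**Figure D4:**
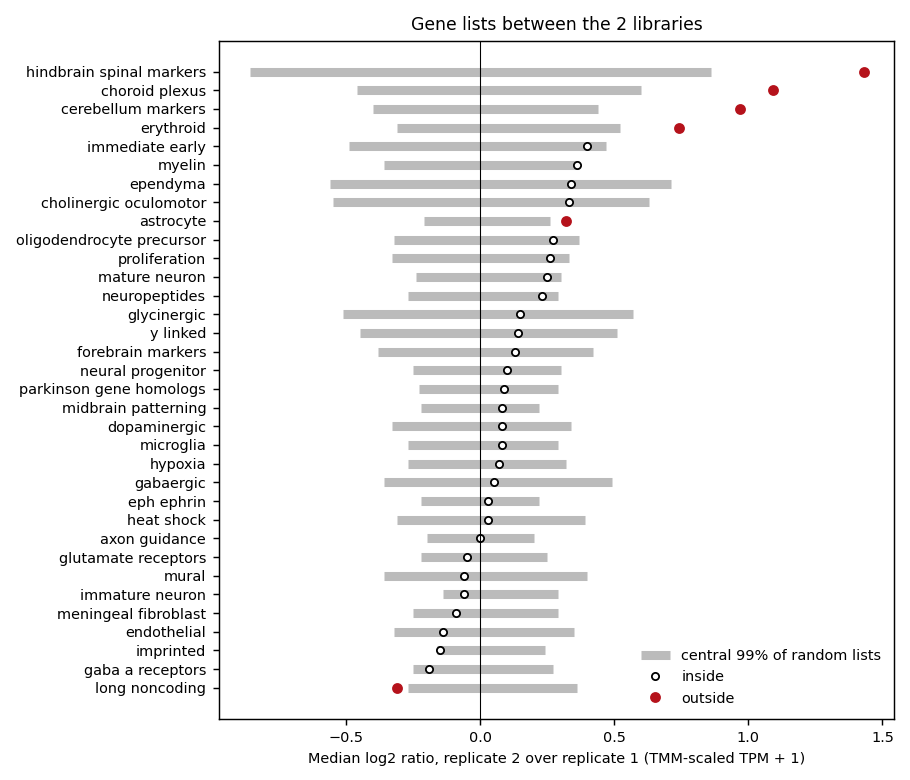
Median log2 ratio of replicate 2 over replicate 1 (TMM-scaled TPM + 1) for 34 gene lists, with grey bars for the central 99% of 10000 random lists of like expression; filled points lie outside. Hindbrain and spinal genes lie highest at 1.43 and long noncoding genes lowest at -0.31.

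The genes with the largest ratios at a mean of 1 TPM or more were mostly pseudogenes or gene models with few counts. Higher in replicate 1 were Gm10231 (103 and 0 counts), Gm27998 (67 and 0), Gm28626 (37 and 0), Gm37376 (37 and 0), Gm16236 (23 and 0), Gm4660 (36 and 1), Gm10478 (26 and 2) and 3 genes without a symbol. Higher in replicate 2 were Gm7336 and Gm12671, with 0 and 422 counts each and equal values, Lce1m, of the skin barrier (0 and 242), Gm28037 (0 and 236), Hoxd3, Gm10443 (0 and 44), Dynlrb2 (1 and 86), Gm29518 (0 and 27), Rpl36a-ps3 (0 and 26) and 1 gene without a symbol. Of these 20 genes, Gm10231, Gm7336, Gm12671, Lce1m, Gm28037, Hoxd3 and 2 without a symbol were called with the spike-in excess, and Gm7336, Gm12671, Lce1m and 1 without a symbol with that of their count range. The deposited credibility bounds of TPM for Gm10231, Gm7336, Gm12671, Lce1m and Rpl36a-ps3 overlapped between the libraries, so these differences are uncertain. Replication-dependent histone genes were called more often in replicate 2, 22 against 1 in replicate 1, and 19 of those higher in replicate 2 were called with the excess of 13.6, but 5 with that of their count range. Xist was higher in replicate 1 (23064 and 15060 counts, log2 ratio -1.22), while Ddx3y (0.10), Uty (0.64), Kdm5d (0.08) and Eif2s3y (0.06) passed no 2-fold call.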

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

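The tests below on the spike-ins were chosen after the spread between the libraries was seen. Reads of the phiX174 phage, a control added at sequencing that no comparison uses, were counted in both libraries, 182140 in replicate 1 and 186094 in replicate 2, or 0.390% and 0.256% of all counts, above the 3 counts that a value of 0 allows. With 2 libraries in 1 group, no library can be tested for standing apart, and no effect can be compared between groups.

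The excess over counting error is given here as the mean chi-square per degree of freedom, a ratio of variances. At summed counts of 20 to 1000 it was 16.2 between the libraries for protein-coding genes. A biological difference between the isolates as the whole of this excess is argued against by 26 spike-ins in the same count range. These do not come from the tissue and had an excess of 13.6, although the labels name the same set for both libraries. Reads shared between near-identical genes as the whole of this are argued against too. All spike-in counts were whole to within 0.005, and the lower end of the bootstrap interval of their excess was 7.67. Spike-ins share no reads with other rows, so they cannot show how much sharing adds among genes. Several counted reads per starting molecule remain a candidate explanation: of 11 spike-ins with a summed count of 20 to 100, 2 were at 0 in 1 library, where independent reads give an expected number of 3.26e-05. Genes such as Gm28626 and Dynlrb2, called on under 100 counts, may therefore show this spread. Differences of the isolates stay open for the genes called with the spike-in excess and for those above 10000 counts. There the excess was 126 for protein-coding genes (bootstrap interval over genes 112 to 142) and 58.1 for spike-ins (26.9 to 99.2). The SD of log2 ratios above 10000 counts was 0.22 and 0.13, against 1.56 and 2.12 at 20 to 1000 counts.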

How the results depend on the processing

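No paired analysis was possible because the labels define 1 group. The alternatives on protein-coding genes alone, spike-in scaling, gene length, the spike-in excess and detection on rescaled TPM were chosen after the data were seen. A result between the 2 libraries cannot be recomputed without either. From a single library, genes at 1 TPM numbered 12351 to 12711, lists 27 to 33 and called pairs 16 to 17, and named genes moved by no more than 1 SD, as a mean of 2 must. The genes detected fell to 6922 at a minimum of 5 TPM and rose to 13336 at 0.5 TPM, 13152 on FPKM and 14892 on rescaled TPM. Lists with a median above the minimum fell from 27 to 16 at 5 TPM and rose to 34 on FPKM and 37 on rescaled TPM. On protein-coding transcripts alone 14 of 18 pairs were called, since Gria2 over Gria1 lost its call and Ndn over H19 could not be compared. Pearson r was 0.918 with a pseudocount of 0.1 and 0.985 without a filter, where rho was 0.951. The coefficient of variation was 0.368 without a filter and 0.198 for protein-coding genes, against 0.226. Genes called as higher in replicate 1 numbered 1587 without a filter (1589 in replicate 2). Genes higher in replicates 1 and 2 numbered 158 and 293 at a summed count of 200, 529 and 806 for protein-coding genes, where fewer genes were tested, 30 and 90 with the spike-in excess, and 11 and 33 with the spike-in excess of their count range. Shares of counts were 76.5% for protein-coding genes, 12.7% for mitochondrial rRNA and 5.27% for small structured RNA, since counts are not divided by length. The same leading transcript was found for 81.9% of genes at 1 TPM and 91.0% at 20 TPM, with median shares of 68.0% and 70.9%. No result reversed. The lists outside their ranges numbered 6 under DESeq2 size factors, a pseudocount of 0.1 and no filter, and 7 without scaling, which shifted the median of all genes by -0.23 and added imprinted genes at -0.42; where no construction is named the cause was not tested.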

Other observations

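Gene families were summed beyond the fixed lists, and were chosen after the data were seen. The 17 tubulin genes summed to 9025 ± 336 TPM. The 102 genes whose symbols begin like those of cytosolic ribosomal proteins summed to 11790 ± 1144, with 96 detected. That set was picked by the start of the symbol and can hold genes of other proteins. All 5 Zic genes were detected, led by Zic1, and 16 of 19 Sox genes, led by Sox4 at 37.2 ± 8.74, Sox11 at 32.7 ± 7.91 and Sox2. Of 57 clustered protocadherin genes, which label individual neurons, 47 were detected, led by Pcdhgc4 at 41.6 ± 4.17 and Pcdhgc3 at 19.2 ± 1.44. Among sodium channels Scn2a led at 33.4 ± 9.09. Of 93 genes with the Kcn prefix of potassium channel genes, 55 were detected. That prefix also takes in genes of channel-interacting proteins such as Kcnip1. Fgf13 led its family at 36.1 ± 12.2, and Wnt7b at 5.04 ± 0.488. None of 1050 olfactory receptor genes was detected, and their summed level was 2.54 ± 0.516.

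Of the tests in this part, those on lists not examined before were fixed first, and those on scaling and noise for hindbrain, cerebellum and choroid plexus genes were chosen after the result was seen. Hindbrain, cerebellar and choroid plexus genes were higher in replicate 2. Over members at 1 TPM in either library, the lowest median log2 ratio of the 3 lists over 3 scalings was 0.80. Leaving out scaling shifted the median of all genes by only -0.23. The lists were taken up for medians of 0.97 or more, so no scaling used here could bring them to 0. These values show that the choice among the 3 scalings matters little, and cannot test scaling further. Hoxb3, Hoxd3 and Hoxa5 pass the filter of 1 TPM through replicate 2 alone. Over all members with counts the hindbrain median was 0.39 at the main scaling. Noise at low counts is argued against for other cerebellar genes by their percentile among random lists, 99.99. On the fixed cerebellar list, 1 of 9 members kept its call with the spike-in excess of its count range (exact p 0.017 before multiplication). At the upper end of the excess 0 did, so noise cannot be told apart from other causes for that list. Noise is argued against for choroid plexus genes too, since 3 of 8, Ttr, Aqp1 and Slc4a5, kept their calls with the spike-in excess of their count range (exact p 0.000660 over all lists and both directions, 0.0127 with 2 calls at the upper end of the excess), although other such genes lay at 80.4 among random lists; it cannot be told apart from other causes for hindbrain genes, where 2 of 12 kept calls (exact p 0.0127, but 0.559 with 1 call at that upper end) and other Hox genes with counts lay at 98.8. More adjacent tissue in the isolate of replicate 2 cannot be told apart from other causes: of 3 lists of other genes, 1 lay above its range, the cerebellar one with Zic2, Gdf10 and Cbln1 at a median of 0.59. That count met the bound set beforehand against this explanation, but the bound was set aside after the result was seen, since 0 of the 18 other Hox genes reached 1 TPM and the other choroid plexus genes, 7 of 12 higher in replicate 2, went both ways; ratios of summed scaled counts were 18.3 (bootstrap interval 3.09 to 266) for other Hox genes, with 62 and 37 of their 139 counts in replicate 2 from Hoxc5 and Hoxd4, but 1.28 (1.01 to 1.82) for other choroid plexus and 1.33 (1.08 to 1.88) for other cerebellar genes.

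Genes of the epidermis were higher in replicate 2, a pattern noticed after the data were seen. Krt10 had 31 and 839 counts in replicates 1 and 2, Krt1 322 and 1890, Krt14 7 and 352, Krt5 0 and 305, Hrnr 0 and 673 and Flg2 0 and 253. These were called also with the spike-in excess, but Krt1 not with that of its count range. In 23 other epidermal genes fixed before they were examined, 18 of the 22 with counts were higher in replicate 2, and 11 passed the exact binomial call, none of them with the spike-in excess. Noise at low counts is argued against by the percentile of their median among random lists, 100. Epidermis in that isolate may be a source but cannot be told apart from others: the ratio of summed scaled counts was 1.63 (bootstrap interval 1.27 to 3.36), which lies on both sides of the bound of 2, and Perp and Sbsn, with 632 and 163 counts in replicate 1, weigh most in it.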
